A study of Mus musculus with 28 samples.

How the data were processed

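The series holds RNA-seq of germinal center B cells from mice, in 28 libraries. Per the labels' genotypes the libraries fall into 6 groups. All carry the Cg1Cre allele, which expresses Cre recombinase in B cells responding to antigen. The groups were heterozygous Tbl1xr1 D370Y (5 libraries), unmutated Tbl1xr1 (called WT here, 3 libraries), heterozygous D370Y with the ImuBcl6 allele (5), ImuBcl6 with unmutated Tbl1xr1 (5), a group labelled homozygous Tbl1xr1 KO (5) and its Cre control (5). The Cre control has the same genotype label as WT and was kept apart because its libraries have a protocol text of their own. Nothing in the labels says which animal gave which library, so every p-value measures the spread between these samples, which may be technical in part.

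Per the labels' protocols, total RNA was extracted with Trizol and an RNeasy kit. A stranded TruSeq kit is named for the KO and Cre control libraries, and the library kit of the other groups was not given in the sources used here. The submitters' processing notes name STAR as the aligner and mm10 as the genome build, without a version. The counting tool, its strand setting and the gene annotation were not given in the sources used here. Reads from overlapping or antisense genes and from near-identical copies could therefore have been shared between symbols. The authors deposited 1 table per library with CPM values for 23382 gene symbols. Every value was a whole multiple of 1 read's worth of CPM, within 0.01 of a read for 100% of the values, so that whole reads could be recovered. The deposited CPM leave part of the denominator outside the list: the reads on listed genes made up 64.4% to 84.6% of the authors' denominator. No immunoglobulin segment symbol is among the listed genes, so a planned recalculation without such genes was not run.

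Of the listed symbols, 22902 (97.9%) matched GENCODE M21, on the assembly that mm10 names, by symbol or 1 older symbol. Coordinates are from that annotation. In the gene lists 7 members were found under an older symbol (Gcet2 for Gcsam, Emr1 for Adgre1, Gm600 for Nuggc, Fam46c for Tent5c, 2010001M09Rik for Mzb1, Igj for Jchain and Beta-s for Hbb-bs), and 3 members were not used here.

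For each comparison log2(CPM + 1) was fitted with limma (version 3.58.1, R 4.3.3) using a mean-variance trend and robust moderation. Genes were kept with a CPM of at least 1 in at least as many libraries as the smallest group of the fit. CPM were used as deposited, without further scaling. Tests were two-sided, and a gene was called at a Benjamini-Hochberg adjusted p below 0.05. Fold changes are on the log2(CPM + 1) scale, which understates the change of genes at low levels. Each allele was compared with its own control in its own fit, and the differences between effects were contrasts in a fit of 4 groups. The D370Y, ImuBcl6 D370Y and KO comparisons share no library.

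Gene lists were fixed before the data were examined. They cover memory, germinal center, dark zone, light zone, plasma cell and naive B cell genes, BCL6 repression targets, the SMRT/NCOR complex, G1/S and G2/M genes, MYC and ribosome biogenesis, interferon response, NF-kB response, MHC class II presentation and B cell receptor signalling. Others hold markers of T cells, myeloid cells, erythroid cells, stroma and endothelium, and immediate early and handling stress genes. These 20 lists were tested with limma's camera at a preset inter-gene correlation of 0.01, adjusted over the lists of each comparison, and again with an estimated correlation. A list needed 3 tested members. The lists overlap in part: the memory list shares 5 genes with the naive list and 5 with the BCL6 target list, and the germinal center list shares 2 with the dark zone list. A further list of 5 sex chromosome genes served only as a check.

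Named genes followed a rule fixed at the same time. For each allele comparison these were Tbl1xr1, Bcl6, the 8 called genes with the largest rise and the 8 with the largest fall at a mean CPM of at least 5, and up to 4 called members of each list. Where a list had no called member, up to 2 members were taken as values. For the other comparisons the limit was 5 genes per direction, and 10 of the shared genes were named. Predicted gene models were left out of the largest rises and falls and of the shared genes named. List members were named under the symbol by which they were found.

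On simulated reads drawn from each comparison's own means, with 100 genes changed 1.5-fold and 100 changed 2-fold, limma recovered 83% and 99% in D370Y against WT, 83% and 98% in the ImuBcl6 background, 74% and 94% in the KO comparison, and 86% and 99% in ImuBcl6 against WT. For the differences of effects it recovered 63% and 91% between backgrounds, and 45% and 84% between the KO and D370Y effects. False calls numbered 5 to 12 per simulation of these 6 comparisons. The changed genes were drawn from those with a mean CPM of at least 5, and each gene's reads were drawn independently. Structure shared by many genes across libraries was not simulated, so false calls could be more numerous in the real data.

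Alternatives were other pseudocounts, filters and scalings, edgeR (version 4.0.16) and DESeq2 (version 1.42.0) on the recovered reads, library weights, replicate blocks, all libraries in 1 fit and leaving out each library in turn. Within each group every pair of libraries differed by more than sampling noise (chi-square per gene 3.69 to 193), so none was counted as a duplicate. This does not show that the libraries came from separate animals. Pairs of WT libraries were among the most alike, at 3.69, 6.34 and 6.61.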

Results

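RNA-seq libraries of mouse germinal center B cells were compared to ask how alleles of Tbl1xr1 change their expression state, with attention to the memory B cell program named in the series title. TBL1XR1 is a WD40-repeat subunit of the SMRT/NCOR corepressor complex, through which BCL6, the main transcriptional repressor of the germinal center, acts on its targets. The 28 libraries had 19.0 to 37.7 M reads on listed genes. The Tbl1xr1 D370Y and WT libraries were the shallowest, at 19.2 to 22.2 and 19.0 to 19.4 M. Both ImuBcl6 groups had 31.8 to 37.7 M, with 27.1 to 34.3 M in the KO and Cre control groups. A limit of 3 reads corresponded to 0.0640 to 0.133 CPM.

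Tbl1xr1 (chromosome 3, 22076652 to 22216594, plus strand) was measured first in every group. Its level was 145.6 ± 11.6 CPM (SD, n = 5) in D370Y and 167.9 ± 10.2 (n = 3) in WT cells. With ImuBcl6, an allele that expresses Bcl6 from an immunoglobulin heavy-chain promoter, it was 98.3 ± 2.43 (n = 5) with D370Y and 128.1 ± 20.6 (n = 5) without. The libraries labelled KO held 102 ± 15.4 CPM (n = 5) and their Cre controls 86.0 ± 5.82 (n = 5). The transcript was thus not lower in the libraries labelled KO (log2 fold change 0.23 ± 0.11 SE, limma adjusted p = 0.527, 95% interval 0.00459 to 0.463). Whole-gene CPM would not show the loss of a single exon, and the deleted part is not given in the sources used here. Bcl6 (chromosome 16, 23965052 to 23988852, minus strand) stood at 362.6 ± 28.9 CPM in D370Y and 362.6 ± 4.18 in WT cells, 467 ± 40.1 and 549.8 ± 24.5 in ImuBcl6 cells with and without D370Y, and 360.9 ± 32.0 and 349.6 ± 24.9 in the KO and Cre control groups.

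Sex-linked transcripts differed between the groups. Xist, the transcript of the inactive X chromosome, lay at 486 to 1460 CPM in all 5 D370Y libraries and at 2.22 to 9.12 CPM in the 3 WT libraries, which expressed the Y-linked Ddx3y, Uty, Kdm5d and Eif2s3y. The ImuBcl6 groups had the opposite arrangement, with the Y-linked genes in all 5 D370Y libraries and Xist in all 5 controls. Among the libraries labelled KO 3 had the Y-linked and 2 the Xist pattern, against 1 and 4 in the Cre controls. Sex and genotype therefore cannot be told apart within either D370Y comparison taken alone, nor in ImuBcl6 against WT.

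**Figure D1:**
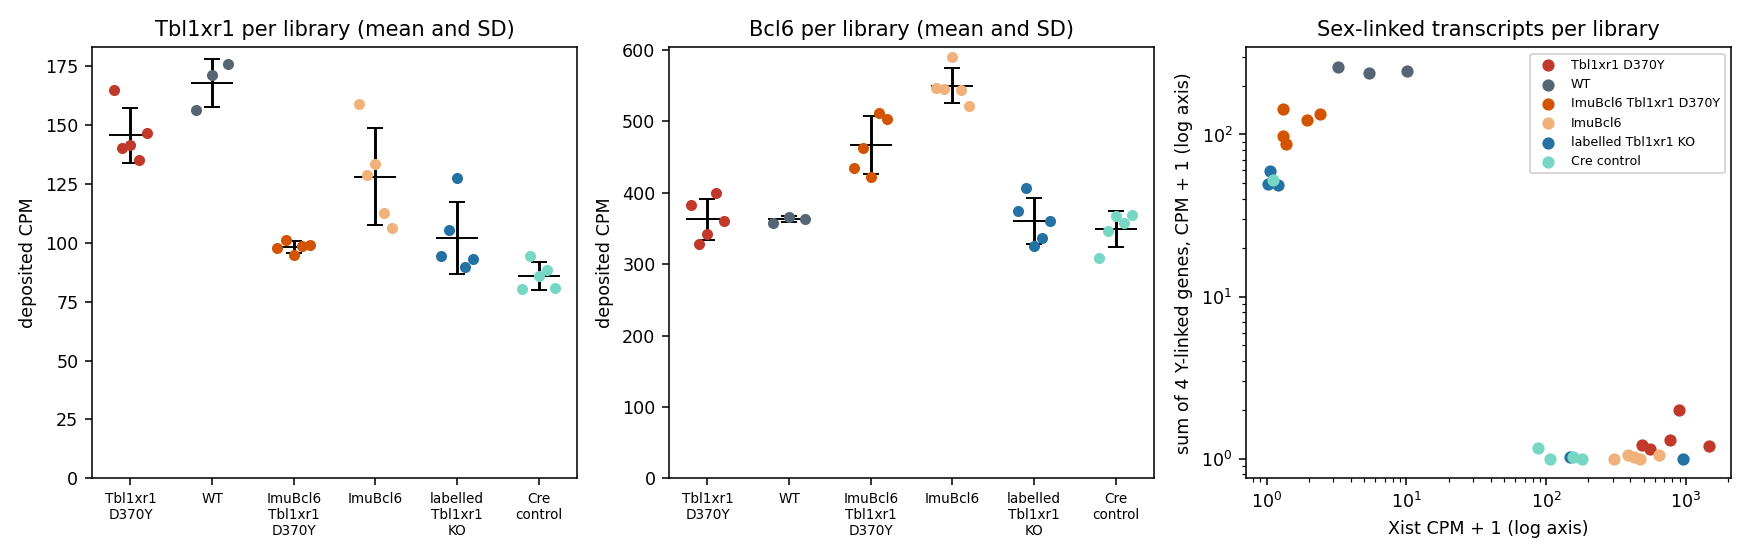
Deposited CPM of Tbl1xr1 (left) and Bcl6 (middle) in each library, with group mean and SD, and Xist against the summed CPM of 4 Y-linked genes on log axes (right). Tbl1xr1 in the libraries labelled KO (89.71 to 127.5 CPM) overlaps the Cre controls (80.55 to 94.53 CPM).

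The first comparison asked what heterozygous D370Y changed in cells without the ImuBcl6 allele. D370Y cells (n = 5) had higher levels than WT (n = 3) of Plac8, a small cysteine-rich protein (chromosome 5, 100553725 to 100572245; 74.2 ± 11.8 against 27.2 ± 1.18 CPM, log2 fold change 1.40 ± 0.11 SE, adjusted p = 3.3e-05). The D-type cyclin Ccnd2 was also higher (46.1 ± 9.95 against 16.7 ± 0.582 CPM, 1.38 ± 0.15, adjusted p = 0.000616). The egress receptor S1pr1 (chromosome 3, 115710433 to 115715072) rose from 36.5 ± 2.33 to 67.7 ± 4.99 CPM (log2 fold change 0.87 ± 0.08, adjusted p = 5.31e-05). Other large rises were in the RNA-binding protein gene Rbm44 (2.03 ± 0.39), Pml, the scaffold of nuclear bodies (1.34 ± 0.22), the scaffold gene Ahnak (1.30 ± 0.25), Emr1, which encodes the macrophage antigen F4/80 (1.30 ± 0.23), and Lgals3bp (1.27 ± 0.27). Among the falls, the cyclic nucleotide phosphodiesterase Pde2a (chromosome 7, 101421691 to 101512827) went from 107.6 ± 5.45 to 59.2 ± 7.37 CPM (-0.86 ± 0.10, adjusted p = 0.000416). Eps8l1 (-0.96 ± 0.16), the corepressor Tle1 (-0.67 ± 0.12) and the small GTPase Rab32 (-0.65 ± 0.15) fell as well. The change in Tbl1xr1 itself (-0.21 ± 0.08, adjusted p = 0.166) and in Bcl6 (0.00 ± 0.07, adjusted p = 0.988) did not pass the test.

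Genes of memory B cells rose as a group and genes of germinal center B cells fell. Naive and myeloid genes rose as well. Values of whole libraries do not tell a changed expression state from a changed mixture of cells, which was not tested. Of the 20 memory genes tested 10 rose and none fell (13 and 1 adjusted over the list alone; camera adjusted p = 8.94e-10, and adjusted p = 0.0373 with an estimated correlation). They included S1pr1, the oxysterol receptor Gpr183 (0.82 ± 0.09), the egress regulator Klf2 (0.75 ± 0.09) and the interleukin-9 receptor gene Il9r (0.90 ± 0.14). Of the 20 germinal center genes 6 fell (10 adjusted over the list alone; camera adjusted p = 1.17e-07, and adjusted p = 0.0373 with an estimated correlation), among them Basp1 (-0.46 ± 0.06), Gm600 (-0.33 ± 0.07), Rassf6 (-0.37 ± 0.08) and the ephrin gene Efnb1 (-0.43 ± 0.10). BCL6 repression targets also moved up, with 8 of 19 rising (9 up and 1 down adjusted over the list alone; camera adjusted p = 7.51e-07, and adjusted p = 0.0261 with an estimated correlation). Those examples were S1pr1, Gpr183, Ccnd2 and the survival gene Bcl2 (0.72 ± 0.11). Naive B cell genes, 5 of which are also memory genes, had 7 of 17 members higher (9 adjusted over the list alone), such as the chemokine receptor Ccr7 (0.95 ± 0.14) and Cd38 (0.60 ± 0.10). That list's camera adjusted p was 3.94e-07, and its call was lost at adjusted p = 0.0822 with an estimated correlation.

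Myeloid markers rose beside these groups, with 5 of 13 higher (10 adjusted over the list alone; camera adjusted p = 1.75e-09, lost at adjusted p = 0.0822 with an estimated correlation). Lyz2 was at 4.25 ± 1.36 against 0.999 ± 0.223 CPM and Emr1 at 10.4 ± 3.59 against 3.43 ± 0.274 CPM, while Itgam (1.38 ± 0.25) and Csf1r (0.93 ± 0.20) also rose. Further lists passed camera at the preset correlation but not with an estimated one. Plasma cell genes had 3 of 20 members higher (10 adjusted over the list alone; adjusted p = 1.76e-05, and 0.301 estimated), namely Cd93 (0.82 ± 0.12), Irf4 (0.52 ± 0.09) and Prdm1 (1.07 ± 0.26), the last pair being regulators of plasma cell differentiation. Interferon response genes had 1 of 17 higher, Bst2 (0.49 ± 0.10), and 7 adjusted over the list alone (adjusted p = 3.08e-06, and 0.301 with an estimated correlation). Dark zone genes had 1 of 18 lower, Gcet2 (-0.48 ± 0.11), and 4 adjusted over the list alone (adjusted p = 0.000893, and 0.301 estimated). The light zone list had Gpr183 and Ccnd2 higher of 19 (2 adjusted over the list alone; adjusted p = 0.0053, and 0.301 estimated). Calls without any member past the all-gene threshold were made for G1/S genes (down, adjusted p = 0.00134, and 0.42 estimated) and G2/M genes (down, 0.000155, and 0.301 estimated). The same held for MHC class II genes (up, 0.00476, and 0.301 estimated), T cell markers (up, 5 tested, 0.0137, and 0.301 estimated) and stroma and endothelium markers (up, 3 tested and 1 higher adjusted over the list alone, 0.0323, and 0.203 estimated). No call was made for SMRT/NCOR (adjusted p = 0.102), MYC and ribosome biogenesis (0.502), NF-kB (0.502), B cell receptor signalling (0.369), erythroid (0.616) or immediate early genes (0.727). Of the immediate early genes 1 fell, Dnajb1 (-0.31 ± 0.07; 1 adjusted over the list alone), and their median (0.0805) and mean (-0.0295) differed in sign.

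In total limma called 376 of 10600 genes between D370Y and WT, 276 higher and 100 lower. The count rested on every WT library: leaving out WT replicate 1, 2 or 3 left 149, 148 or 124 genes. It was 219 without the low-value filter, 249 with all 28 libraries in 1 fit, 659 by DESeq2 and 973 with library weights, and 20 of the 376 genes lay on chromosomes X and Y (11.8 expected).

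Adding the same D370Y allele to ImuBcl6 cells gave the second comparison (5 libraries per group). The scavenger receptor and fatty acid transporter Cd36 (chromosome 5, 17781690 to 17888801) was higher with D370Y, at 100.9 ± 14.8 against 40.9 ± 14.0 CPM (log2 fold change 1.33 ± 0.19, adjusted p = 0.00189). Also higher were Plac8, from 56.3 ± 11.2 to 142 ± 66.0 CPM (1.25 ± 0.23, adjusted p = 0.00699), the interferon-inducible GTPase Iigp1 (1.23 ± 0.18) and Emr1 (1.22 ± 0.26). The cadherin Celsr1 (chromosome 15, 85898929 to 86033777) fell from 20.4 ± 3.25 to 7.01 ± 1.94 CPM (-1.44 ± 0.17, adjusted p = 0.00078). Large falls were also seen in the peptide transporter Slc15a2 (-1.87 ± 0.29), Eepd1 (-1.51 ± 0.25), Vopp1 (-1.30 ± 0.20) and the retinaldehyde reductase Dhrs3 (-1.30 ± 0.16). Tbl1xr1 fell by 0.37 ± 0.09 on the log2 scale (adjusted p = 0.0261, or 0.0544 without the low-value filter) and Bcl6 fell by 0.24 ± 0.06 (adjusted p = 0.0344).

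Memory genes rose again, with 7 of 20 higher and none lower (9 and 1 adjusted over the list alone; camera adjusted p = 1.77e-07, lost at adjusted p = 0.0903 with an estimated correlation). Cd38 went from 54.7 ± 4.56 to 114.8 ± 25.7 CPM (1.03 ± 0.13) and Bcl2 from 7.01 ± 1.69 to 15.7 ± 2.04 CPM (1.08 ± 0.14), with Gpr183 (1.17 ± 0.16) and S1pr1 (0.68 ± 0.10) also higher. Germinal center genes had 8 of 20 lower (12 adjusted over the list alone; camera adjusted p = 1.13e-06, lost at adjusted p = 0.0903 with an estimated correlation), led by Gcet2 (-0.78 ± 0.12), Basp1 (-0.80 ± 0.13), the plexin Plxnb2 (-0.39 ± 0.07) and Gm600 (-0.34 ± 0.06). Dark zone genes had 6 of 18 lower (10 adjusted over the list alone), including the translesion polymerase Polh (-0.42 ± 0.08), the chemokine receptor Cxcr4 (-0.40 ± 0.09) and Racgap1 (-0.24 ± 0.06), with a camera adjusted p of 9.72e-05 that was lost at adjusted p = 0.0903 with an estimated correlation. The naive list held its call under both settings (8 of 17 higher, 12 adjusted over the list alone; camera adjusted p = 2.16e-10, and 0.0341 with an estimated correlation), with Gimap6 (0.43 ± 0.07) among its members.

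Markers of other cell types again moved alongside. Myeloid markers had 6 of 11 higher (7 adjusted over the list alone; camera adjusted p = 7.41e-07, and 0.0341 with an estimated correlation), including Itgam (1.15 ± 0.17), Vcam1 (0.67 ± 0.14) and Lyz2 (3.92 ± 0.948 against 1.91 ± 0.554 CPM). Of 5 T cell markers 2 rose, Cd3g (5.96 ± 2.67 against 1.48 ± 0.670 CPM) and Cd2 (0.46 ± 0.07); adjusted over the list alone these 2 rose and 1 fell (adjusted p = 0.0315, and 0.231 estimated). Of 2 stroma and endothelium genes tested 1 rose, Pecam1 (0.42 ± 0.12; 1 adjusted over the list alone), too few for a list test. The remaining calls were lost with an estimated correlation. BCL6 targets had 5 of 19 higher and 1 lower (6 and 1 adjusted over the list alone, adjusted p = 0.0116, and 0.0911 estimated), with the cell cycle inhibitor Cdkn1b at 0.48 ± 0.09. In the SMRT/NCOR complex Tbl1xr1, Bcl6 and Bcor (-0.29 ± 0.08) fell, 3 of 12 (6 adjusted over the list alone, adjusted p = 0.0273, and 0.319 estimated). G1/S genes had 2 of 18 lower, Uhrf1 (-0.26 ± 0.07) and Cdc6 (-0.20 ± 0.06; 3 adjusted over the list alone, adjusted p = 0.0116, and 0.319 estimated). G2/M genes had 3 of 18 lower (3 adjusted over the list alone, adjusted p = 0.0103, and 0.319 estimated): Bub1b (-0.24 ± 0.05), Cdca8 (-0.23 ± 0.05) and Aurkb (-0.21 ± 0.05). Plasma cell genes had 3 of 19 higher (3 adjusted over the list alone, adjusted p = 0.0331, and 0.319 estimated), Ly6c2 (0.68 ± 0.12), 2010001M09Rik (0.26 ± 0.06) and Sec11c (0.26 ± 0.06). MHC class II genes had 1 of 12 higher, the protease Ctss (0.25 ± 0.06; 1 adjusted over the list alone, adjusted p = 0.0302, and 0.461 estimated). No call was made for light zone (adjusted p = 0.108), interferon (0.492), NF-kB (0.699), MYC and ribosome biogenesis (0.54), B cell receptor (0.693), erythroid (0.594) or immediate early genes (0.594). Single members of these that passed were Gpr183 of the light zone list, Gbp2 (0.44 ± 0.10) and Usp18 (-0.59 ± 0.14) of the interferon list, Tnf (0.53 ± 0.12) and Tnfaip3 (-0.30 ± 0.07) of the NF-kB list, and Dusp1 (-0.77 ± 0.20) of the immediate early list. The NF-kB list had a median of -0.0499 and a mean of 0.0116.

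Limma called 882 of 10784 genes, 302 higher (34.2%) and 580 lower, of which 42 lay on chromosomes X and Y (27.4 expected). Without ImuBcl6 D370Y replicate 2 or 3, or ImuBcl6 replicate 3, 546, 501 or 434 genes were called. DESeq2 called 1378 genes (45.3% higher), and CPM recomputed over the reads on listed genes gave 44.7% higher among 816.

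**Figure D2:**
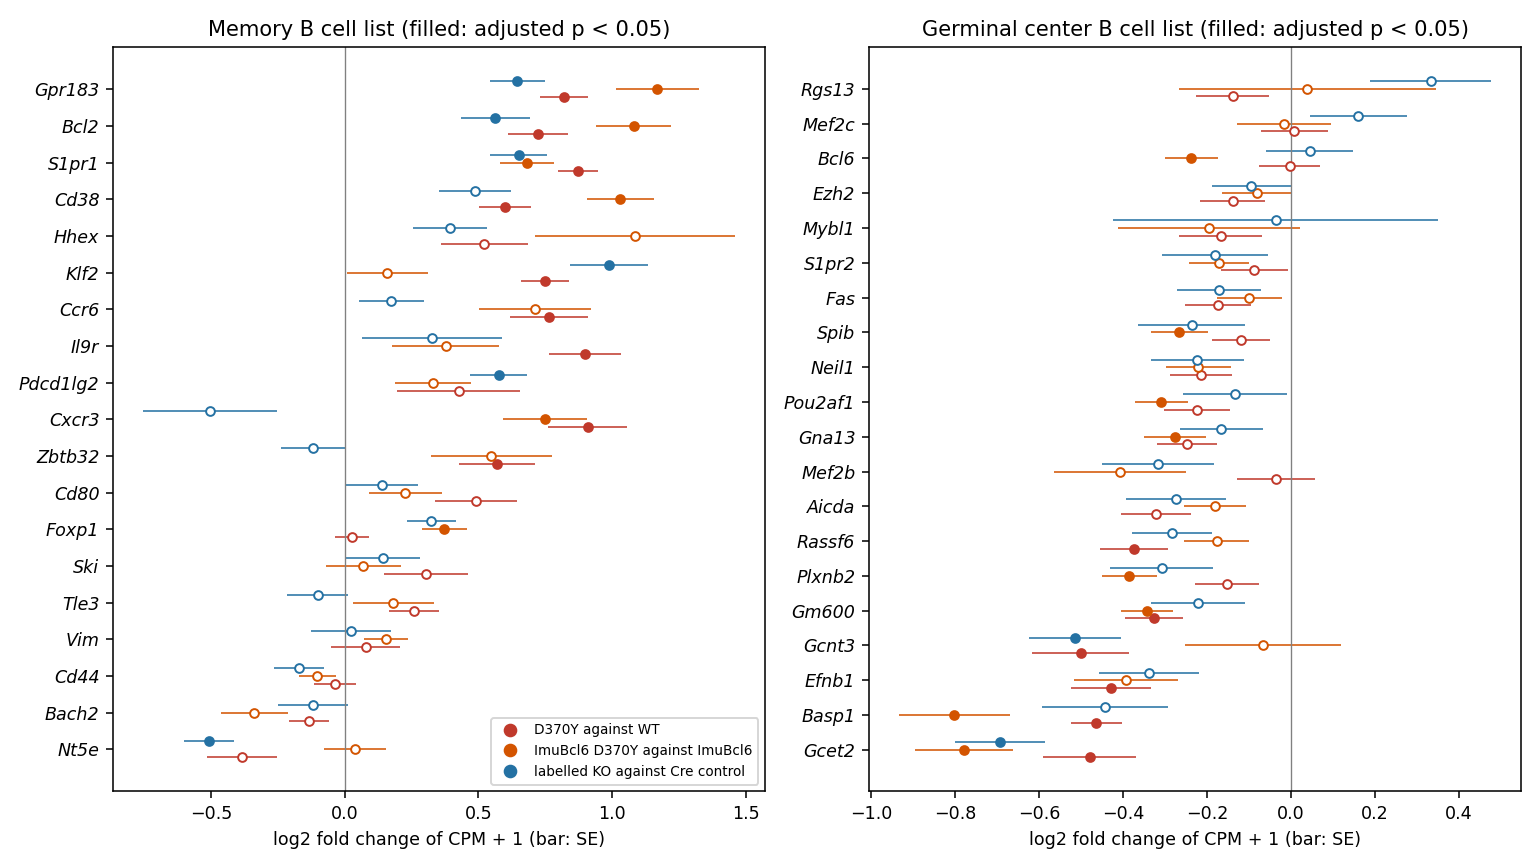
Log2 fold change of CPM + 1 (points, with SE bars) for genes of the memory (left, 19 of 20 shown) and germinal center (right) lists in D370Y against WT, ImuBcl6 D370Y against ImuBcl6, and libraries labelled KO against Cre control. Filled points have a limma adjusted p below 0.05. Over the whole lists 10, 7 and 5 memory genes rose, and 6, 8 and 2 germinal center genes fell.

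The third comparison set the libraries labelled KO against their Cre controls (5 per group), with the reservation that the target transcript was not lower. Cd36 rose from 10.3 ± 1.91 to 30.2 ± 6.44 CPM (log2 fold change 1.46 ± 0.15, adjusted p = 4.77e-05) and Klf2 from 25.3 ± 2.69 to 52.3 ± 13.5 CPM (0.99 ± 0.15, adjusted p = 0.0013). Other rises were in the transcription factor Zeb2 (1.14 ± 0.12), the sialyltransferase St3gal6 (1.01 ± 0.13), the cholesterol efflux transporters Abca1 (0.93 ± 0.17) and Abcg1 (0.84 ± 0.12), the lipase Mgll (0.89 ± 0.13) and the adaptor Grap2 (0.84 ± 0.11). Celsr1 fell from 25.2 ± 4.98 to 9.84 ± 1.36 CPM (-1.26 ± 0.13, adjusted p = 5.89e-05) and Pde2a from 101.3 ± 13.5 to 46.9 ± 10.9 CPM (-1.12 ± 0.15, adjusted p = 0.000394). Myzap (-1.13 ± 0.14), the oxysterol-binding protein gene Osbpl3 (-1.10 ± 0.13), Palm (-1.07 ± 0.14), the actin bundler Fscn1 (-1.01 ± 0.13), Unc13a (-0.93 ± 0.12) and Dhrs3 (-0.93 ± 0.11) were lower too. Bcl6 did not pass the test (0.04 ± 0.10, adjusted p = 0.933).

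Naive B cell genes formed the list that held its call under both settings, with 4 of 17 higher (11 adjusted over the list alone; camera adjusted p = 1.44e-16, and 0.0397 with an estimated correlation): Klf2, S1pr1 (0.65 ± 0.11), the adaptor Bank1 (0.53 ± 0.10) and the complement regulator Cd55 (0.55 ± 0.13). Memory genes had 5 of 20 higher and 1 lower (9 and 1 adjusted over the list alone; camera adjusted p = 4.75e-09, lost at adjusted p = 0.15 with an estimated correlation), with Gpr183 higher (0.65 ± 0.10) and the ectonucleotidase gene Nt5e lower (-0.51 ± 0.09). Of the germinal center genes Gcet2 (-0.69 ± 0.11) and Gcnt3 (-0.51 ± 0.11) fell, 2 of 20 (5 adjusted over the list alone; camera adjusted p = 0.000159, lost at adjusted p = 0.42 with an estimated correlation). BCL6 targets had 3 of 19 higher, Gpr183, S1pr1 and Bcl2 (0.56 ± 0.13; 3 adjusted over the list alone, adjusted p = 0.00147, and 0.267 estimated). Stroma and endothelium markers were called higher with 3 tested and none past the all-gene threshold (1 adjusted over the list alone, adjusted p = 0.0111, and 0.267 estimated), Cdh5 being nearest (0.51 ± 0.14, adjusted p = 0.0755). Myeloid markers were not called (none of 13 past the threshold, adjusted p = 0.285), nor were T cell (0.261) or erythroid markers (0.261). The dark zone (adjusted p = 0.168, Gcet2 lower, 2 adjusted over the list alone), light zone (0.792, Gpr183 higher) and plasma cell lists (0.31) were not called. In the last, Cd93 was higher at 0.56 ± 0.12 and Fam46c lower at -0.56 ± 0.11 (1 and 2 adjusted over the list alone). No call was made either for SMRT/NCOR (0.529), G1/S (0.529), G2/M (0.724), MYC and ribosome biogenesis (0.703), interferon (0.0546, Ifit3 higher at 0.74 ± 0.18), NF-kB (0.175), MHC class II (0.79), B cell receptor (0.936) and immediate early genes (0.317). The light zone (median -0.0325), immediate early (-0.0749), myeloid, SMRT/NCOR, G2/M, MYC, MHC class II and B cell receptor lists had medians below 0 with a camera direction up, beside a median of -0.0609 over all tested genes. Those directions go with no call.

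Limma called 146 of 10514 genes, 50 higher (34.2%) and 96 lower. KO replicate 3 stood apart from the group, with 64.4% of the denominator on listed genes against 82.6% to 84.6% in the other KO libraries and Malat1 at 1633 CPM. Without that library 449 genes were called, and the memory and naive lists had 8 higher each. The call of the BCL6 target list was lost without it (3 of 19 higher, camera adjusted p = 0.155). The count was 87 without Cre control replicate 2 and 90 without Cre control replicate 3, and median-ratio scaling gave 244 genes with 49.6% higher.

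The 3 allele comparisons share no library, so their overlap could be counted directly. In all 3, 33 of 10100 genes were called in the same direction, 23 higher (0.0344 expected of independent lists) and 10 lower (0.0462 expected). Cd36 had log2 fold changes of 1.02 ± 0.24 in D370Y, 1.33 ± 0.19 in ImuBcl6 D370Y and 1.46 ± 0.15 in the KO comparison, and Zeb2 had 0.99 ± 0.10, 1.18 ± 0.16 and 1.14 ± 0.12. Tmem26, Adam19, Gpr183, St3gal6, Grap2, Bcl2 and Ptpn22, a phosphatase of antigen receptor signalling, were also higher in each, and Pde2a was lower in each (-0.86 ± 0.10, -0.70 ± 0.12 and -1.12 ± 0.15). Between pairs of comparisons, D370Y and ImuBcl6 D370Y shared 95 genes higher (7.56 expected) and 22 lower (5.35 expected), with 19 in opposite directions (17.4 expected). The 19 include Y-linked genes, as the sexes are reversed between these comparisons and 4 genes on chromosome Y were called in each. A sex effect acting alike in both would put genes in opposite directions. The genes shared in direction therefore argue against such an effect as the cause of their change. D370Y and KO shared 31 (1.22 expected) and 22 (0.877 expected) with none opposite (2.78 expected). ImuBcl6 D370Y and KO shared 35 (1.39 expected) and 47 (4.98 expected) with 1 opposite (5.26 expected). Across genes, which are not independent replicates, the fold changes correlated with Pearson's r of 0.402, 0.459 and 0.454 (Spearman's rho 0.308, 0.417 and 0.305). Xist, Tsix and 4 Y-linked genes were left out of these correlations, though not of the counts. Without the low-value filter 14 genes were shared by all 3. The shared count was 18, 14 or 16 without WT replicate 1, 2 or 3, and 54 without KO replicate 3.

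**Figure D3:**
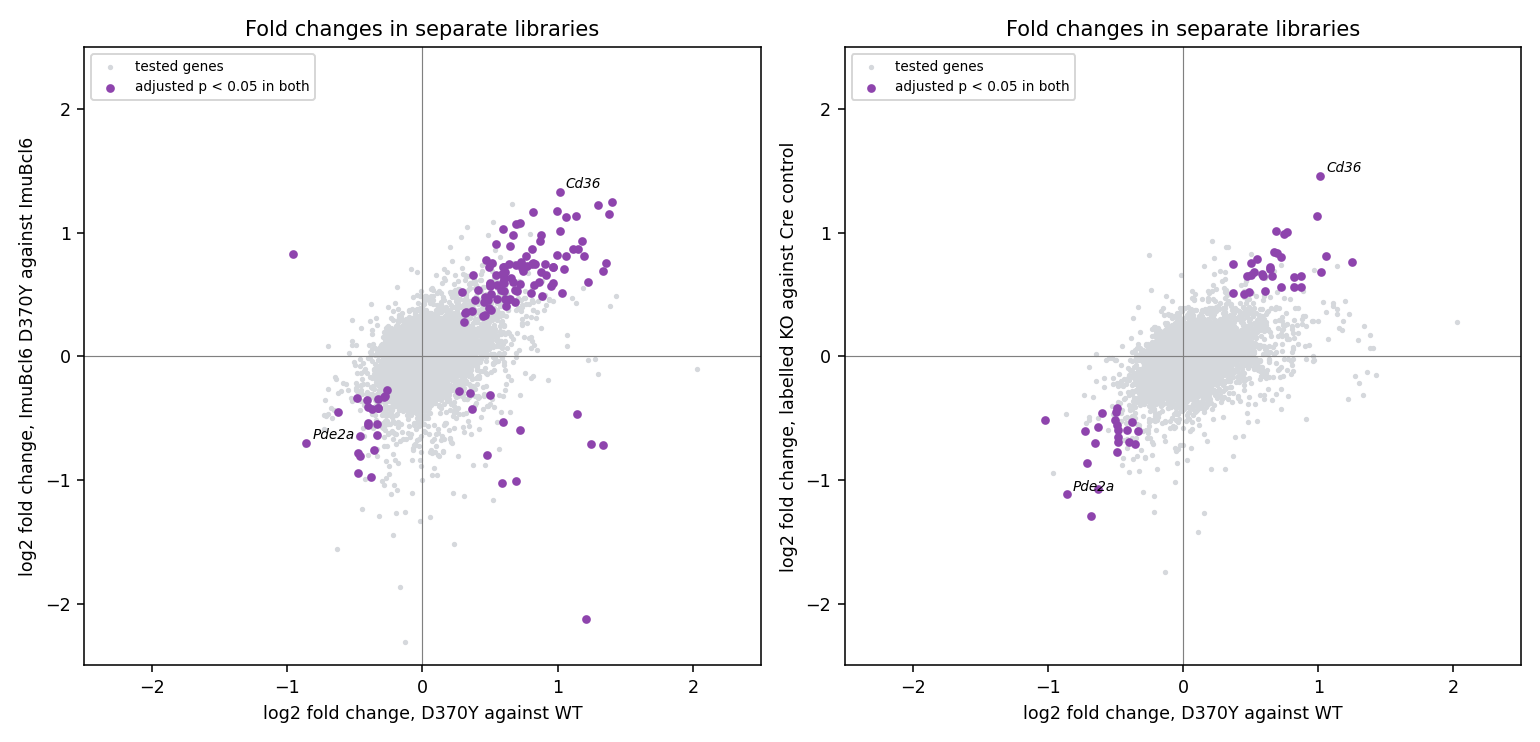
Log2 fold change of CPM + 1 per gene in D370Y against WT (x axis) against ImuBcl6 D370Y against ImuBcl6 (left) and libraries labelled KO against Cre control (right), leaving out Xist, Tsix and 4 Y-linked genes. Purple points passed limma's test in both comparisons; Cd36 was higher and Pde2a lower in all 3.

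Whether the effect of D370Y differed between the backgrounds was tested as a contrast of 4 groups. Eps8l1 fell in cells without ImuBcl6 and rose with it (0.83 ± 0.22), a difference of 1.79 ± 0.31 (adjusted p = 0.00583). Emp2, a tetraspan membrane protein gene, fell with ImuBcl6 (-2.31 ± 0.20) and was at -0.13 ± 0.22 without it (difference -2.18 ± 0.32, adjusted p = 0.000758), and Eepd1 had a difference of -1.74 ± 0.35 (adjusted p = 0.0212). The X-linked demethylase gene Kdm6a, which escapes X inactivation, differed by -1.70 ± 0.17 (adjusted p = 2.44e-06). Tbl1xr1 did not differ past the threshold (-0.16 ± 0.13, adjusted p = 0.642). The interferon list was lower in the difference (none of 17 members past the threshold, 3 lower adjusted over the list alone; camera adjusted p = 0.00211, lost at adjusted p = 0.936 with an estimated correlation). No difference was called for the memory (adjusted p = 0.817), germinal center (0.763), naive (0.326), BCL6 target (0.326) or myeloid list (0.567). Limma called 74 of 11166 genes, 10 higher and 64 lower, of which 18 lay on chromosomes X and Y (2.35 expected). The sexes of the groups are arranged in opposite ways in both backgrounds, so they are part of this contrast. Without D370Y replicate 1 or 2 the count was 49 or 46, without WT replicate 1 or 3 it was 33 or 31, and without ImuBcl6 D370Y replicate 5 or ImuBcl6 replicate 2 it was 47 or 43.

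The effect in the libraries labelled KO was set against the D370Y effect in the same way. Plac8 (difference -1.34 ± 0.20, adjusted p = 0.00208), Ccnd2 (-1.32 ± 0.18, adjusted p = 0.000453) and the annexin partner S100a10 (-0.96 ± 0.19, adjusted p = 0.0388) rose in D370Y cells and had KO values of 0.06 ± 0.14, 0.07 ± 0.09 and 0.22 ± 0.14. The fatty acid receptor Ffar2 differed by -0.93 ± 0.15 (adjusted p = 0.00622). Celsr1 fell in the libraries labelled KO and was at -0.22 ± 0.15 in D370Y cells (difference -1.04 ± 0.21, adjusted p = 0.0431). Tbl1xr1 did not pass this test (0.44 ± 0.14, adjusted p = 0.328). The myeloid gene Lyz2 and Ccnd2 were the list members past the threshold. Lists lower in the KO effect than in the D370Y effect included plasma cell (adjusted p = 2.83e-09, lost at 0.279 with an estimated correlation), myeloid (2.84e-08, lost at 0.259), BCL6 target (0.000641, lost at 0.212) and memory genes (0.0102, lost at 0.459). Adjusted over the list alone 8 plasma cell, 3 myeloid, 2 BCL6 target and 4 memory genes were lower, and 1 memory gene was higher. Light zone (0.00195), interferon (0.00311), NF-kB (0.0325) and MHC class II genes (0.0447) were lower too, and G2/M (0.000641), G1/S (0.0241) and SMRT/NCOR genes (0.0315) higher, none of them with an estimated correlation. Limma called 16 of 11041 genes, 3 higher (18.8%) and 13 lower, and median-ratio scaling called 9 with 33.3% higher. Of the 16 genes 3 lay on chromosomes X and Y (0.5 expected, Fisher's exact p = 0.0125), and the sexes of the D370Y and WT groups are part of this contrast too. Counts without 1 library ran from 7 (without WT replicate 1 or 3) to 63 (without D370Y replicate 5). They were 10 without D370Y replicate 2, KO replicate 1, KO replicate 5 or Cre control replicate 3, 9 without Cre control replicate 2 or 5, 29 without KO replicate 3 and 27 without Cre control replicate 4.

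ImuBcl6 cells were compared with WT for the effect of the Bcl6 allele on unmutated Tbl1xr1. Bcl6 was higher with it (log2 fold change 0.60 ± 0.05, adjusted p = 6.02e-06) and Tbl1xr1 lower (-0.40 ± 0.11, adjusted p = 0.0125). In the Cre controls, which lack that allele, Bcl6 was at 349.6 ± 24.9 CPM, against 362.6 ± 4.18 in WT. Tbl1xr1 was at 86.0 ± 5.82 CPM there, below the 128.1 ± 20.6 of ImuBcl6 cells, so its fall cannot be assigned to the Bcl6 allele. All 5 ImuBcl6 libraries had the Xist pattern and all 3 WT libraries the Y-linked pattern, so sex is part of this comparison too. Interferon genes had 15 of 17 members higher (15 adjusted over the list alone; camera adjusted p = 1.36e-06, lost at adjusted p = 0.646 with an estimated correlation). MYC and ribosome biogenesis genes had 12 of 18 higher and 1 lower (12 and 1 adjusted over the list alone; adjusted p = 0.000918, lost at 0.646), and naive genes 1 of 17 higher and 12 lower (1 and 12 adjusted over the list alone; adjusted p = 0.00793, lost at 0.646). G1/S genes (9 of 18 higher and 1 lower; the same counts adjusted over the list alone; adjusted p = 0.0464, lost at 0.646) and immediate early genes (8 of 14 higher and 1 lower; 8 and 2 adjusted over the list alone; adjusted p = 0.0113, lost at 0.84) were also called. Cre control against WT, where neither group has the Bcl6 allele, moved most of these lists in the same direction. Camera called immediate early genes there (adjusted p = 0.00604, and 0.553 with an estimated correlation). It did not call MYC and ribosome biogenesis (0.0733), naive (0.0722) or G1/S genes (0.0988). That comparison called 8276 of 10720 genes, so counts of called members are high in any list. Higher and lower members numbered 13 and 4 of 18 for MYC and ribosome biogenesis and 3 and 11 of 17 for naive genes. For G1/S genes they were 12 and 4 of 18, and for immediate early genes 11 and 0 of 14. Interferon genes had 3 and 3 of 15. The moves of the lists other than interferon therefore cannot be assigned to the Bcl6 allele. Interferon genes also rose in D370Y against WT, with the same WT libraries, the same arrangement of sexes and no Bcl6 allele. Their median log2 fold change was 0.479 there (camera adjusted p = 3.08e-06, and 0.301 with an estimated correlation) and 0.814 in ImuBcl6 against WT. The interferon rise cannot be assigned to the Bcl6 allele either. Some genes with large rises were almost absent from WT libraries, among them the sorting nexin Snx22 (141.2 ± 14.9 against 0.362 ± 0.137 CPM) and the immediate early factor Fos (179.2 ± 24.3 against 1.05 ± 0.367). Among genes named for the largest falls, Crisp3 was the one that is not Y-linked (-2.68 ± 0.18). In all, 5802 of 10889 genes were called, 2691 higher and 3111 lower. Fos was at 1.15 ± 0.131 CPM in the D370Y libraries and at 92.3 ± 25.1 in the Cre controls, whose genotype label is that of WT, so that the low level goes with the D370Y and WT libraries rather than with the Bcl6 allele.

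**Figure D4:**
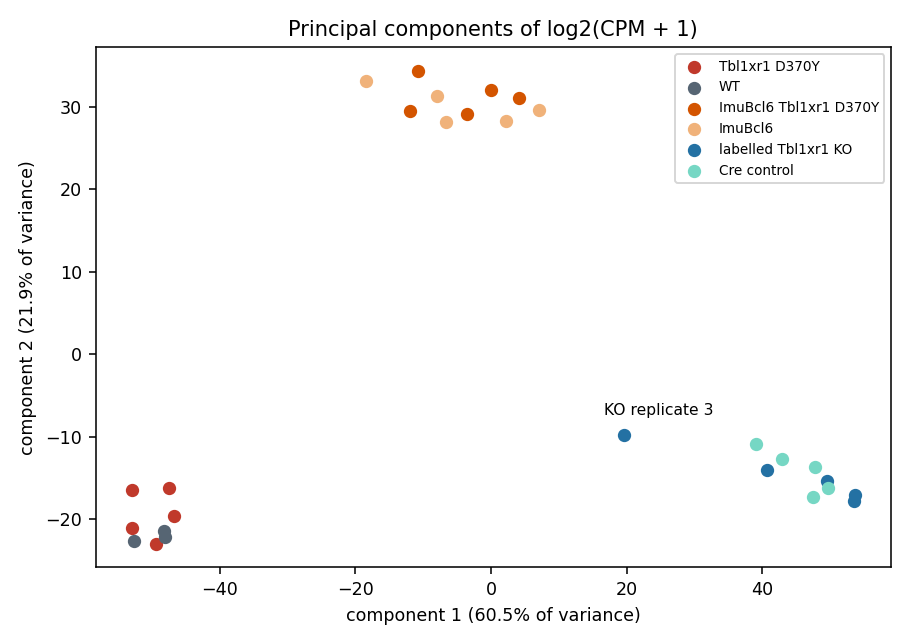
Principal components 1 (60.5% of variance) and 2 (21.9%) of log2(CPM + 1) for the 28 libraries, coloured by group. The D370Y and WT libraries, the ImuBcl6 groups and the KO and Cre control libraries lie in 3 separate clusters, and KO replicate 3 lies apart from its group.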

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

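The tests on sex, sets of libraries, GC content, label swaps and scaling were chosen only after the results were seen, as was the contrast of mean D370Y effects with its splits. The thresholds for the other splits were written after the counts of called genes were known, but before any split was run. Within groups of 5, a library's gap to its nearest neighbour, as a share of the group's range, was compared with Dixon's critical value of 0.71. Over 120 such tests 12 exceeded it, where chance gives about 5% of tests.

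KO replicate 3 was far from its group in the share of reads on listed genes (ratio 0.899) and in the means of the light zone (0.844), G1/S (0.754), MYC and ribosome biogenesis (0.732), MHC class II (0.784) and B cell receptor lists (0.791). D370Y replicate 4 stood apart in the share on listed genes (0.86). ImuBcl6 D370Y replicate 1 did so for the G1/S (0.717) and NF-kB lists (0.718) and ImuBcl6 replicate 1 for the G1/S list (0.71). Erythroid genes set apart D370Y replicate 5 (0.765) and KO replicate 4 (0.744). Of 127 named genes, 1 library stood apart for 12 in D370Y, 13 in ImuBcl6 D370Y, 7 in ImuBcl6, 12 in KO (10 of them in replicate 3) and 7 in the Cre control.

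The D370Y effect differed between backgrounds for 74 genes, by the test of the difference itself. Among them Eps8l1 (1.79), Emp2 (-2.18), Eepd1 (-1.74) and Kdm6a (-1.70) were the named genes other than Xist, Tsix and the Y-linked ones. For genes on X and Y, the sex of the animals may account for the difference, since 18 of the 74 lie there (Fisher's exact p = 1.03e-11). For autosomal genes sex and background cannot be told apart. The difference correlated with the sex effect in the KO and Cre control libraries at r = 0.249 across 10051 genes, but 5 of 50 assignments of sex gave as high a value, and 62.5% of 48 called genes moved the same way. Over those 48 genes alone the correlation was -0.0847.

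Of the 74 genes, 56 are autosomal and 39 were called with X and Y genes left out. Of 100 splits 2 gave as many, the real one included, but the highest other split called 320 genes. That points to a structure of the samples that crosses genotype, so chance alignment with it was not excluded. An action of the Bcl6 allele itself stays open.

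ImuBcl6 against WT called 5802 genes, far more than any comparison of alleles, and none of 56 splits other than the real one called a gene (highest other 0). With each library taken as a separate unit, a chance split was excluded, as 1 split gave as many. The labels do not name the animals, so chance differences between animals are not covered. The labels give no batch between both groups, but a difference between sets of libraries other than the Bcl6 allele is a candidate explanation for part of the count: the called genes moved alike between the KO and D370Y libraries, which share no library with the comparison and carry no Bcl6 allele (r = 0.727, and 73.8% in the same direction). GC content as the whole cause is argued against, as 79.7% of the called genes were still called after a GC trend was removed from each library. Sex as the whole cause is argued against too: in D370Y against WT, with the sexes arranged alike and the same WT libraries, the called genes moved in their own direction by a median of 0.0661 log2 units against 0.48 (a share of 0.138, or 0.0894 to 0.164 without each library in turn). An effect of the Bcl6 allele stays open, though not for the high level of Fos and Snx22 as a whole, which were high in the Cre control libraries without it.

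Tbl1xr1 was not lower in the libraries labelled KO. A swap of some labels between the KO and Cre control groups is argued against: on the genes called in both D370Y comparisons (95 higher, 22 lower) the lowest KO library lay 0.611 log2 units above the highest Cre control library (exact permutation p = 0.00794, the smallest that 5 against 5 can give). Scaling is argued against as well, since the log2 fold change was no lower than 0.115 over 24 alternatives (adjusted p 0.191 to 0.858). The separation shows that both groups differ, not which allele they carry. A deletion that leaves most of the transcript in place could give this picture and was not tested, as no exon-level values were used here.

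The KO and D370Y effects differed for 16 genes, of which Plac8 (-1.34), Ccnd2 (-1.32), Celsr1 (-1.04), S100a10 (-0.96) and Ffar2 (-0.93) were the named autosomal ones. For that count 1 of 100 splits gave as many, but the highest other split called 11, so the margin is small.

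With each library taken as a separate unit, a chance split was also excluded for the 376 genes of D370Y against WT (1 of 56 splits, highest other 12). The same held for the 146 of libraries labelled KO against Cre control (1 of 100, highest other 2). Libraries from the same animal would not be separate units, and the labels do not name the animals. For the 33 shared genes 1 of 100 splits gave as many (highest other 0). Other splits of each allele comparison called a median of 0 genes, so the split test of the shared count adds no separate support. For the 882 genes of ImuBcl6 D370Y against ImuBcl6, 1 of 100 splits gave as many. Another split, of D370Y replicates 1 and 2 with ImuBcl6 replicates 1, 2 and 3 against the rest, called 858. That structure crosses genotype, so chance alignment with it was not excluded. In both D370Y comparisons and ImuBcl6 against WT the real split also parts the sexes, so these counts do not speak to genotype alone. For the number of lists called, 1 of 56 splits gave as many as the 14 lists of D370Y against WT, which met the threshold set. The other splits called up to 13 lists, with a median of 6, so the margin is small and chance is not firmly excluded. It could not be excluded in the ImuBcl6 background (12 lists, 5 of 100 splits, highest other 14, median 4). The same held in the libraries labelled KO (5 lists, 25 of 100 splits, highest other 10, median 2).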

How the results depend on the processing

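Alternatives that left out X and Y genes, used sex as a covariate, recomputed CPM over the reads on listed genes, left out KO replicate 3 from lists or together with median-ratio scaling, left out each library from the shared genes, and all those of the mean D370Y contrast were chosen after seeing the data. Where a value moved, the cause was not tested. For D370Y against WT (376 genes) the count was 219 without a filter, 659 by DESeq2, 973 with library weights and 249 with all 28 libraries. ImuBcl6 D370Y (882) moved to 1378 by DESeq2. Libraries labelled KO against Cre control (146) moved to 86 without a filter, 244 by median-ratio scaling, 240 by quantile normalization (44.6% higher), 238 by edgeR (49.2%), 455 by DESeq2 (50.5%), 1111 with library weights, 279 with all 28 libraries, 239 with CPM on listed genes (48.5%), and 513 with median-ratio scaling and KO replicate 3 left out. The difference between backgrounds (74) moved to 49 without a filter, 184 by DESeq2 (29.3% higher), 197 with library weights and 39 without X and Y genes. The difference of KO and D370Y (16) moved to 32 with a pseudocount of 5, 7 at a CPM of at least 5, 9 by median-ratio scaling, 9 by quantile normalization, 5 by edgeR, 43 by DESeq2 and 211 with library weights. The mean D370Y contrast (1397) moved to 2167 with library weights. Shared genes (33) numbered 14 without a filter. List calls over the 3 allele comparisons (31) fell to 6 with an estimated correlation, and to 6 with KO replicate 3 left out as well.

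The labels number replicates alike in each group, and a block on that number was planned. The numbers do not pair the libraries: each had its highest correlation with its own number in 3 of 13 pairs. With the block, D370Y against WT called 764 genes, the difference between backgrounds 133 and the difference of KO and D370Y 64. It moved no other count by over 1.5 times. Among lists, D370Y against WT lost the dark zone (adjusted p = 0.0874), light zone (0.227), G1/S (0.187) and MHC class II calls (0.0854) with the block and gained B cell receptor signalling (0.0436), and the libraries labelled KO gained the interferon list (0.0198).

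Leaving out 1 library gave 124 to 473 genes for D370Y against WT, 434 to 1016 for ImuBcl6 D370Y, 87 to 449 for KO, 4525 to 6417 for ImuBcl6 against WT, 31 to 110 for the difference between backgrounds, 7 to 63 for KO against D370Y effects, 896 to 1482 for the mean contrast (896 and 928 without WT replicate 2 and 3) and 14 to 54 for shared genes. Of the named genes past the threshold, the call was lost in some such fit for 15 of 36, 17 of 53 and 6 of 27 in the 3 allele comparisons, and none changed sign. Over all pairs of a named gene and a setting, the gene kept its side of the threshold in 5860, lost the call in 428 and gained it in 62. The 5860 count a gene called in neither fit as kept, even where its sign changed. In 2 further pairs a called gene changed sign. Both were Eif2s3y of the mean contrast, which went from -1.02 to 0.91 by edgeR (adjusted p = 0.553) and 1.08 by DESeq2 (adjusted p = 0.245). ImuBcl6 against WT stayed within 1.5 times of 5802 under every alternative run.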

Other observations

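Averaging the effect of D370Y over both backgrounds, a contrast chosen after the data were examined, puts D370Y and control libraries of both sexes on each side, so that a sex effect that adds equally in both backgrounds cancels. Y-linked genes did not meet that condition. Their summed CPM was 237 to 260 in WT and 86.4 to 143 in ImuBcl6 D370Y libraries, and 3 genes on chromosome Y were still called. Part of a sex effect can therefore remain in this contrast. Memory genes rose in 13 of 20 (14 up and 1 down adjusted over the list alone; camera adjusted p = 2.97e-11, and 0.00771 with an estimated correlation), with S1pr1 at 0.78 ± 0.07, Cd38 at 0.82 ± 0.09 and Bcl2 at 0.90 ± 0.10 (log2, SE). Germinal center genes fell in 11 of 20 (15 adjusted over the list alone; camera adjusted p = 6.69e-10, and 0.0107 estimated), including Basp1 (-0.63 ± 0.08) and the coactivator Pou2af1 (-0.27 ± 0.05). Naive genes rose in 11 of 17 (12 adjusted over the list alone; 3.77e-12, and 0.00467 estimated) and BCL6 targets in 8 of 19 (9 up and 1 down adjusted over the list alone; 1.04e-05, and 0.00413 estimated). Tbl1xr1 itself was lower (-0.29 ± 0.06, adjusted p = 0.00541). Myeloid markers rose beside these groups in 10 of 13 (11 adjusted over the list alone; 3.77e-12, and 0.00467 estimated), Lyz2 by 1.06 ± 0.13, as did 2 of 3 stroma and endothelium markers (2 adjusted over the list alone; 0.00666, and 0.0402 estimated), of which Pecam1 was at 0.34 ± 0.09. T cell markers rose in 2 of 6 (4 adjusted over the list alone; 0.00296, lost at adjusted p = 0.142 with an estimated correlation), Cd3g and Cd2. A changed mixture of cells was not told apart from a changed expression state here either.

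The contrast called 1397 of 11166 genes, 696 higher and 701 lower. At a mean CPM of at least 5 the largest rises were Plac8 (1.33 ± 0.15), Emr1 (1.26 ± 0.19), Cd36 (1.17 ± 0.16), Zeb2 (1.09 ± 0.11), S100a10 (1.05 ± 0.12), the metalloprotease Adam19 (1.02 ± 0.14), Pml (1.01 ± 0.14) and the Fc receptor-like gene Fcrl5 (1.01 ± 0.11). The largest falls outside sex-linked genes were Emp2 (-1.22 ± 0.16), Slc15a2 (-1.02 ± 0.20), Celsr1 (-0.83 ± 0.13), Dhrs3 (-0.81 ± 0.13), Slc16a3 (-0.79 ± 0.26) and Pde2a (-0.78 ± 0.09). Genes on X and Y made up 40 of the called genes (44.4 expected). Of 100 splits 1 gave as many, but the highest other split called 901 genes, so chance alignment with a structure of the samples was not excluded.

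Cre control and WT libraries have the same genotype label, and their comparison was also added after the data were examined. It called 8276 of 10720 genes, with Snx22 at 164.6 ± 5.58 against 0.362 ± 0.137 CPM and Samd9l lower by a log2 fold change of -4.36 ± 0.17. Levels of these groups are therefore not set beside each other as effects of an allele.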
